A study of Fragaria x ananassa with 28 samples.

How the data were processed

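Groups (the injected solution and the day) and replicate numbers come from the sample labels. Per the labels, RNA of 10 fruits per group was extracted separately and pooled in equal amounts, and whether the 2 libraries of a group came from separate pools is not given in the sources used here. The labels' protocols speak of 7 mRNA libraries, while 14 samples and columns are given, and of 100 bp paired reads, while the statistics table lists 125 bp clean reads.

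mRNA values are RPKM, reads per kilobase of transcript scaled to the counted reads, made by the authors on a de novo transcript assembly, per the file headers and the Trinity sequence file the labels name. The aligner, counter and settings are not given in the sources used here. RPKM times length came out as whole reads (within 0.1 of a read) for 100% of values, which were 13.4% to 15.1% of clean reads, so that 1 read on 1 kb was worth 0.111 to 0.136 RPKM. The table held 301219 transcripts in 98600 assembly components, 130654 of them with a Swiss-Prot description, and 8 lines without a transcript name were not analysed here. Forms of a component can be alleles, copies from the subgenomes or splice forms, and reads shared between them make single forms uncertain.

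miRNA values are reads scaled to the clean reads of the library (RPM), although the sheet the authors deposited is called RPKM: per the file headers each column is a library, and values times the stated clean reads were whole in 12 of 14 libraries. Water day 5 replicate 2 and NDGA day 8 replicate 2 had 16.8% and 18.8% whole values and were scaled to another total, and were used as deposited. Known miRNAs took 8.96% to 22.7% of clean reads. The smallest value above 0 was 7 to 13 reads, so a 0 is not a count of 0. Of 371 names, 46 were at 0 in every library. The miRNA database and aligner are not given in the sources used here. miRNAs given only as group means were not used here. The authors' lists, clusters and miRNA calls were set beside the values only in the closing section.

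Transcripts with RPKM of 1 or more in at least 2 libraries (99136, 34209 of them described) were tested with limma on log2(RPKM + 1) over all 14 libraries and 7 groups, with a trended prior (7 residual and 6.05 prior df), no covariate and Benjamini-Hochberg adjustment within each of 11 comparisons. miRNAs with RPM of 10 or more in at least 2 libraries (165) were tested in the same way on log2(RPM + 1) in 8 comparisons (1.15 prior df). SEs are those of the fit. The test, groups, 30 gene lists, 15 miRNA families, naming rule and the alternatives not said below to be added were fixed before the data were examined. Lists took described transcripts by keyword, and lists of seed, xylem and cuticle transcripts stand for other tissues. A list of virus proteins had 0 tested members. The other 29 were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. Of the families, 10 had 3 or more tested names.

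Transcripts were named by a rule for 5 comparisons (day 8 against day 0 in water, and ABA and NDGA against water at both days). From each list it took the member with the smallest adjusted p below 0.05 and a mean RPKM of 5 or more in the higher group, or, where none passed, the most abundant member. It added the 3 rising and 3 falling described transcripts with the largest change among those passing with a mean RPKM of 10 or more in the higher group, without uncharacterized proteins. For miRNAs it took the 5 higher and 5 lower names with the smallest adjusted p below 0.05.

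Alternatives were another pseudocount, no filter or one 5 times stricter, quantile normalization, rescaling to a common sum, the replicate number as a block, a fit of the compared groups alone, for lists only the most abundant transcript of each description, and each library left out. Added after the data were seen were limma's voom on recovered reads (the weights above the 99th percentile of reads capped), median-ratio scaling, sums per component, a set without 297 transcripts following the seed storage list (correlation over 0.9), and, for miRNAs, names above 0 in all libraries, the 2 rescaled libraries left out, and sums or the highest value over names of a number. Libraries of a group differed by more than sampling noise (median chi-square 1.22 to 1.64 against 0.455), and every mRNA library was closest to its own replicate (0.912 to 0.921, against at most 0.896 between groups), as were 8 of 14 small RNA libraries, but neither those of water at day 5 nor any of NDGA.

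The fit was tested on simulated data made from ABA against water at day 8. Of 50 transcripts each changed by 1, 2, 3 and 4 (log2) among 99136, it called 40%, 98%, 98% and 100%, and 10 of 178 calls were unchanged transcripts. Of 200 changed miRNAs each, summed over repeated runs on the 165 names, it called 0.5%, 20%, 37.5% and 54%. So the miRNA test missed many changes of each size. Over these runs, 1, 7, 5 and 7 unchanged names were called beside 1, 40, 75 and 108 changed ones. Tools were R 4.3.3, limma 3.58.1 and the data.table package, version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.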

Results

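The series followed ripening of the receptacle, the fleshy part of the fruit, in 'Toyonoka', an octaploid cultivar of the cultivated strawberry (Fragaria × ananassa). Fruit 2 weeks past flowering were injected with 100 µL of water, of 1 µM abscisic acid (ABA, a hormone known to promote strawberry ripening) or of 100 µM nordihydroguaiaretic acid (NDGA). NDGA blocks ABA synthesis, per the labels, and is also known as a general inhibitor of lipoxygenases. Water-injected fruit were taken at days 0, 5 and 8, and ABA- and NDGA-injected fruit at days 5 and 8, which gives 7 groups. Each group had 2 polyA mRNA libraries and 2 small RNA libraries, 28 in all. The mRNA libraries held 7356752 to 9035037 counted reads on assembled transcripts, and the small RNA libraries 1556032 to 3395145 reads on known microRNAs (miRNAs). Levels below are RPKM (reads per kilobase, scaled to the counted reads) as mean±SD with n = 2 libraries per group, and changes are on the log2(RPKM + 1) scale, which understates the change of low transcripts. Each transcript is named by the Swiss-Prot protein its description gives, with the identifier in brackets at first mention. RNA of 10 fruits per group was pooled, per the labels, so p-values measure only the spread between these libraries, which may be technical.

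Of 99136 tested transcripts, 10464 differed between days 8 and 0 in water-injected fruit, 4832 higher and 5632 lower (limma, adjusted p below 0.05). ABA changed 2146 transcripts against water at day 5 and 13163 at day 8, and NDGA changed 2015 at day 5 and 2164 at day 8. Fits of the compared groups alone gave 823 between days 8 and 0, 10 and 1135 for ABA, and 22 and, with limma, 0 for NDGA (12583 at an unadjusted p below 0.05), and 105 of 167 calls on the transcripts named for these 5 comparisons missed the threshold.

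**Figure D1:**
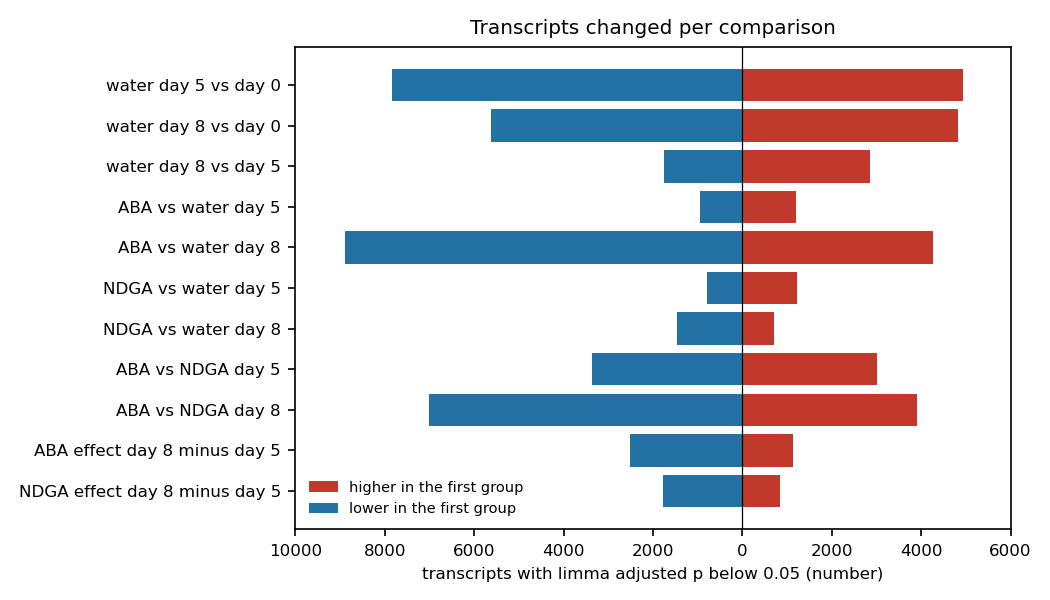
Number of transcripts with a limma adjusted p below 0.05 in each of 11 comparisons (x axis, number of transcripts), with red bars to the right for transcripts higher in the first-named group and blue bars to the left for those lower.

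The first comparison, day 8 against day 0 in water-injected fruit, describes ripening without a treatment. Pigment and aroma transcripts rose. The transcription factor MYB113 (comp93382_c0_seq1), whose relatives switch on anthocyanin genes, rose from 0.208±0.294 to 127±10.9 RPKM, a log2 change of 6.75±0.21 (SE, adjusted p = 3.6e-10). The flavonoid enzyme naringenin,2-oxoglutarate 3-dioxygenase (comp105084_c0_seq1) rose from 86.1±9.37 to 335±29.6, and phenylalanine ammonia-lyase 1 (comp105622_c0_seq2), the entry enzyme of the phenylpropanoid pathway, from 4.99±0.172 to 26.7±0.553. The quinone oxidoreductase-like protein At1g23740 (comp99435_c1_seq1), of a family that includes the strawberry enzyme forming the aroma compound furaneol, rose from 14.4±0.983 to 362±15.1. Of 115 flavonoid transcripts, 31 rose and 13 fell (43 and 19 adjusted over the list alone, adjusted p = 5.9e-04). Of 79 aroma transcripts, 15 rose and 5 fell (16 and 7 adjusted over the list alone, adjusted p = 0.00504, but adjusted p = 0.0821 with an estimated correlation).

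Seed storage transcripts fell, with a list median of -3.62 (log2). Legumin A (comp113743_c1_seq5) fell from 2459±458 to 1.90±1.22 RPKM, legumin B (comp115929_c3_seq2) from 2256±98.6 to 2.49±0.793, vicilin (comp99556_c1_seq5) from 1426±55.3 to 0.720±0.334 and a vicilin-like antimicrobial peptide (comp99556_c0_seq1) from 1393±75 to 0.698±0.00580. These proteins are stored in seeds, which in strawberry lie in the achenes on the receptacle surface. Of 91 seed storage and oil body transcripts, 72 fell and 3 rose (74 and 6 adjusted over the list alone, adjusted p = 4.9e-63). Their share of all RPKM was 1.92%±0.137 at day 0, 0.507%±0.00474 in water at day 5 and 0.0319%±7.49e-04 at day 8 (SD, n = 2). Dehydrin DHN1 (comp97672_c0_seq2) fell from 95.3±12.6 to 0.527±0.323, with 31 of 49 late embryogenesis abundant and dehydrin transcripts falling and 3 rising (35 and 4 adjusted over the list alone). An ABSCISIC ACID-INSENSITIVE 5-like protein (comp100986_c0_seq1) stood at 26.7±1.2 at day 0 and was listed at 0 in both day 8 libraries. Likewise listed at 0 at day 8 were the AP2-like factor AIL1 (comp88053_c1_seq1, 13.2±0.0933 at day 0) and non-specific lipid-transfer protein 3 (comp95265_c0_seq1, 115±21.4). Abscisic acid 8'-hydroxylase 2 (comp56854_c0_seq1) fell from 8.50±0.466 to 0.126±0.179, and 3 of 27 ABA synthesis and breakdown transcripts fell with 0 rising (0 and 4 up and down adjusted over the list alone). That list call (adjusted p = 0.0287) was lost with an estimated correlation (adjusted p = 0.0821), without water day 0 replicate 1 (adjusted p = 0.0983) and without water day 8 replicate 2 (adjusted p = 0.0767).

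By day 8, expansin-A8 rose in 2 assembled forms, from 0.965±0.00552 to 305±35.9 (comp105538_c0_seq2) and from 1.01±0.60 to 233±24 (comp105538_c0_seq5). The pectin and hemicellulose list was not called, with 63 rising and 70 falling of 428 (83 and 97 adjusted over the list alone). Cellulose synthase A subunit 5 (comp108462_c0_seq1) fell from 752±47.4 to 305±10.2 and xylem serine proteinase 1 (comp111480_c0_seq9) from 300.3±32.1 to 79.9±1.56, while caffeic acid 3-O-methyltransferase (comp98837_c1_seq1) rose from 182±9.43 to 513±75.7 in a list that fell. Falling against rising members numbered 24 and 1 of 84 for cellulose, 31 and 6 of 133 for lignin, 14 and 1 of 69 for xylem and 46 and 13 of 187 for the cuticle. Adjusted over the list alone, the falling and rising counts were 30 and 3, 36 and 7, 15 and 1, and 59 and 19. Histone transcripts rose in 95 of 165 and fell in 1 (113 and 3 adjusted over the list alone), with histone H4 (comp101474_c0_seq5) at 394±31.9 and then 2826±53.4. Cyclin-A3-2 (comp117700_c0_seq12) was listed at 0 at day 0 and stood at 17.7±0.261 at day 8, while cyclin-D3-1 (comp110005_c1_seq1) fell from 118±2.13 to 14.6±0.0126. AGL21 (comp121586_c0_seq1), a MADS-box factor, was listed at 0 and then stood at 11.6±0.347. Ribosomal protein transcripts rose in 145 of 712 and fell in 5, heat shock transcripts in 57 and 20 of 252, and light-harvesting and photosystem transcripts in 24 and 12 of 120. Their counts adjusted over the list alone were 180 and 8, 71 and 24, and 36 and 13. 60S ribosomal protein L5 (comp104209_c0_seq1) rose from 100.1±10.7 to 284±18.5, heat shock cognate 70 kDa protein 2 (comp117136_c0_seq4) from 338±10.4 to 1519±40.4, and chlorophyll a-b binding protein 21 (comp96419_c0_seq1) from 78.9±7.29 to 622±32.7.

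Hormone and sugar lists mostly fell in the same comparison. DELLA protein SLR1 (comp116278_c0_seq2) fell from 167±32.6 to 28.4±4.74 and TIFY 11A (comp104462_c1_seq3) from 56.5±1.41 to 9.23±1.26, whereas auxin-induced in root cultures protein 12 (comp101076_c0_seq2) rose from 94.7±11.8 to 427±15.2. Sucrose synthase 2 (comp56326_c0_seq1) fell from 20.1±2.03 to 0.114±0.161 and squamosa promoter-binding-like protein 14 (comp119627_c0_seq1) from 118±1.55 to 69.9±0.158. Falling and rising members were 56 and 19 of 263 for auxin, 22 and 9 of 83 for gibberellin and 15 and 6 of 81 for lipoxygenases and jasmonate. They were 26 and 5 of 120 for sugars, 16 and 0 of 39 for squamosa promoter-binding factors and 14 and 4 of 83 for MADS-box factors. All were called as falling, the last with adjusted p = 0.0705 with an estimated correlation. Adjusted over the list alone, the falling counts were 69, 24, 19, 30, 22 and 19. Lists not called, with their rising and falling members, were ABA signalling (14 and 11 of 117), ethylene (23 and 37 of 235), starch (4 and 8 of 56) and NAC factors (8 and 18 of 126). The others not called were MYB and bHLH factors (24 and 23 of 272), defence (22 and 26 of 212), the phenylpropanoid entry (4 and 10 of 45), housekeeping (31 and 35 of 238) and the cell cycle (19 and 8 of 125). Adjusted over the list alone these counts were 16 and 12, 27 and 46, 4 and 13, 10 and 24, 29 and 28, 26 and 34, 5 and 18, 36 and 41, and 22 and 11. Single members that passed were granule-bound starch synthase 1 (comp107842_c1_seq2, 572±37.2 to 312±9.54), NAC domain-containing protein 18 (comp120044_c1_seq9, 357±20.6 to 822±35.6), major allergen Pru av 1 (comp101722_c0_seq4, 2644±33.4 to 4541±61.1) and actin (comp97795_c0_seq3, 230.0±10.6 to 87.7±3.13). The adjusted p-values (limma) of the named transcripts were 1.5e-12 to 1.6e-04. Leaving out water day 0 replicate 1 or 2, or water day 8 replicate 1 or 2, gave 6932, 6604, 6181 and 6366 transcripts.

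By day 5, 12766 transcripts differed from day 0 in water-injected fruit (4933 higher, 7833 lower), against 4629 between days 5 and 8 (2865 higher, 1764 lower). MYB113 stood at 8.71±1.22 at day 5, and naringenin,2-oxoglutarate 3-dioxygenase at 37.5±1.78, lower than at day 0 (log2 change -1.17, adjusted p = 7.5e-06) before its rise by day 8. Flavonoid transcripts rose in 24 of 115 from day 5 to day 8 and fell in 1 (30 and 1 adjusted over the list alone, adjusted p = 2.0e-09). Leaving out water day 0 replicate 2, or water day 5 replicate 1 or 2, gave 7877, 7445 and 7487 transcripts for day 5 against day 0. For day 8 against day 5, leaving out water day 5 replicate 1 or 2, or water day 8 replicate 1 or 2, gave 2219, 2110, 2475 and 2354. With only the compared groups in the fit the counts were 998 and 45.

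**Figure D2:**
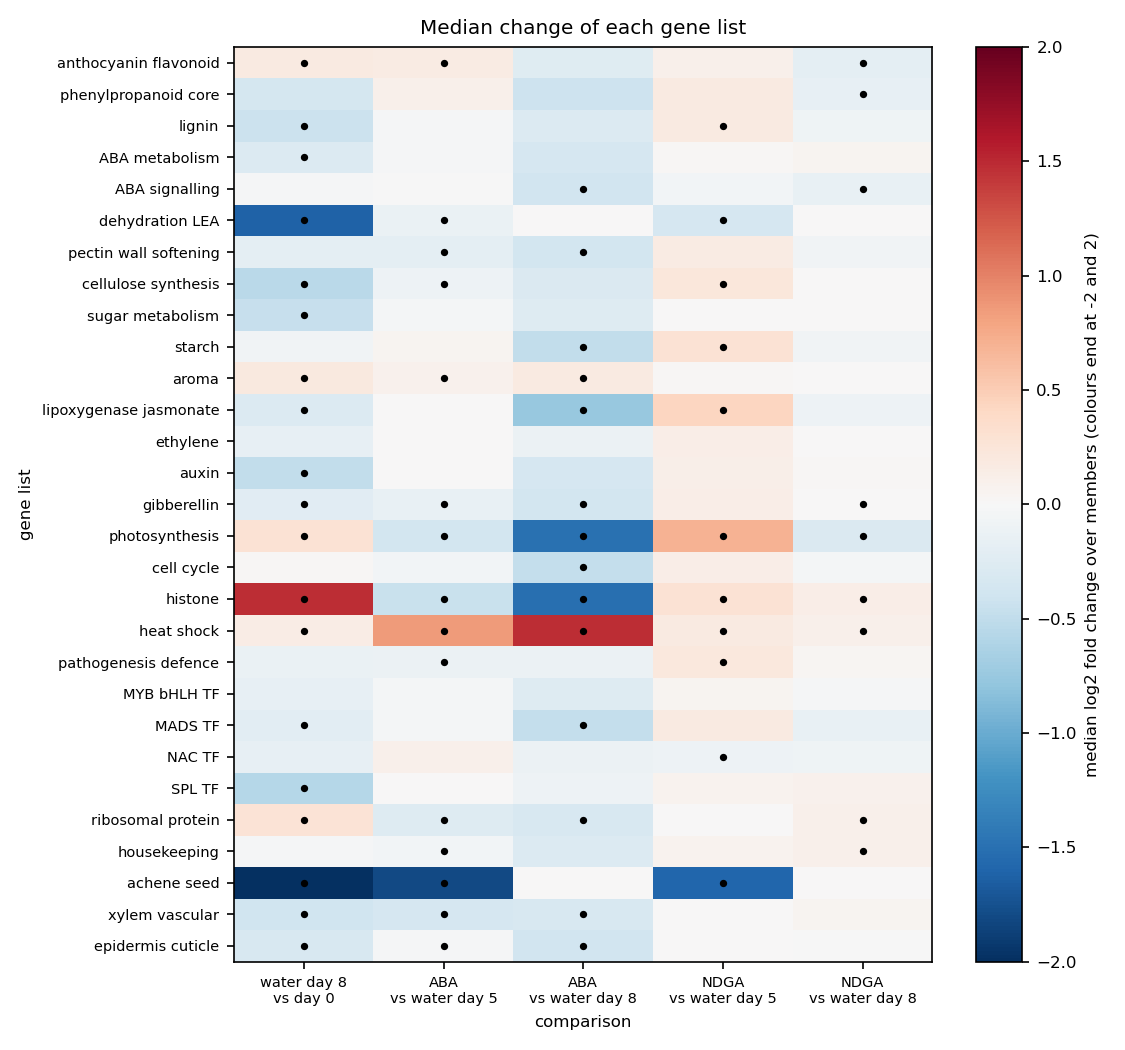
Median log2 fold change over the tested members of each gene list (y axis) in 5 comparisons (x axis), with colour from blue (lower in the first-named group) to red (higher), ending at -2 and 2, and a dot where camera called the list (adjusted p below 0.05).

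ABA against water at day 5 asked what added ABA changes early, and 1198 transcripts were higher and 948 lower. Higher with ABA were MYB113 at 53.9±2.56 against 8.71±1.22 RPKM, naringenin,2-oxoglutarate 3-dioxygenase at 177±6.66 against 37.5±1.78 (log2 change 2.21±0.10, SE) and the At1g23740-like quinone oxidoreductase at 208±5.59 against 40.3±4.64. Flavonoid transcripts were higher in 17 of 115 and lower in 0 (26 and 2 adjusted over the list alone, adjusted p = 3.5e-07). Aroma transcripts were higher in 10 of 79 and lower in 1 (11 and 1 adjusted over the list alone), a call with adjusted p = 0.0670 with an estimated correlation. Heat shock transcripts were higher in 88 of 252 and lower in 1 (127 and 6 adjusted over the list alone, adjusted p = 6.8e-50), and held 3.86%±0.208 of all RPKM against 1.24%±0.0393. A 70 kDa heat shock protein (comp109644_c1_seq1) stood at 560.2±27.9 against 30.8±0.552 and a small chloroplast heat shock protein (comp101496_c0_seq2) at 373±20.5 against 6.53±1.91. A class III small heat shock protein (comp104790_c0_seq4) stood at 202±25.6 against 4.51±1.60 and a class I one (comp94345_c0_seq2) at 58.7±4.70 against 0.628±0.169.

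Seed storage transcripts were lower with ABA at day 5 in 47 of 91 and higher in 1 (52 and 3 adjusted over the list alone), with 0.0262%±9.05e-04 of all RPKM against 0.507%±0.00474. Legumin B stood at 1.63±0.304 against 493±24.8, legumin A at 1.26±0.978 against 447±11.3, and 2 forms of the 11S globulin G3 were listed at 0 against 396±22.9 (comp115929_c3_seq1) and stood at 0.329±0.0194 against 447±45.8 (comp94194_c0_seq2). Dehydrin DHN1 was lower too (0.311±0.0183 against 26.0±5.23), with 5 of 49 in its list lower and 0 higher. Lower against higher members numbered 23 and 1 of 165 for histones, 71 and 3 of 712 for ribosomal proteins and 17 and 2 of 120 for photosynthesis. They were 9 and 0 of 69 for xylem, 15 and 0 of 212 for defence and 29 and 15 of 428 for wall softening. All were called as lower. Adjusted over the list alone, the lower counts were 9 for dehydrins and, in the order above, 45, 135, 30, 12, 18 and 53. Their named members were histone H4 (1000.3±38.9 against 1858±43.3), 60S acidic ribosomal protein P1-3 (comp115302_c1_seq11, 1139±33.6 against 1625±60.9) and chlorophyll a-b binding protein P4 (comp95310_c0_seq1, 85.8±5.86 against 255±7.86). Others were fasciclin-like arabinogalactan protein 4 (comp108868_c0_seq1, 58.0±4.04 against 142±5.46), Pru av 1 (436±2.14 against 1317±35.9), and a probable xyloglucan endotransglucosylase (comp103646_c4_seq1, 37.2±6.27 against 159±9.73).

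Other changes with ABA at day 5 included lower gibberellin-regulated protein 6 (comp100015_c0_seq1, 3.46±0.690 against 31.0±1.56), tubulin beta-6 (comp94311_c0_seq1, 539.6±8.91 against 1370.0±6.15) and cellulose synthase A subunit 5 (202±0.937 against 325±0.587). A GDSL lipase of the cuticle list (comp106832_c0_seq1, 46.1±3.37 against 79.5±4.63) and inactive beta-amylase 9 (comp113657_c0_seq2, 5.15±0.164 against 24.6±0.128) were also lower. The jasmonate repressor TIFY 5A (comp89542_c0_seq1) was higher (19.4±0.164 against 2.20±0.255). The sugar transporter SWEET10 (comp10412_c0_seq1, 0.248±0.351 against 6.91±0.439), an auxin-repressed protein (comp112534_c0_seq6, 47.0±6.07 against 97.7±4.32), MADS-box protein CMB1 (comp107794_c0_seq2, 594±28.7 against 858±33.0) and NAC transcription factor 29 (comp103951_c0_seq1, 20.2±1.21 against 52.3±0.917) were lower. The ABA receptor PYL12 (comp99969_c0_seq2) was lower (10.0±1.46 against 24.2±0.705) and an ethylene-forming 1-aminocyclopropane-1-carboxylate oxidase (comp98989_c0_seq1) higher (39.1±7.93 against 11.1±0.165). Without water day 5 replicate 2 their adjusted p was 0.0608 and 0.0560, and without ABA day 5 replicate 1 it was 0.0692 and 0.0766. Cyclin-D3-1 (16.3±0.116 against 34.5±3.05) missed the threshold without water day 5 replicate 2, or ABA day 5 replicate 1 or 2 (adjusted p = 0.0978, 0.0660 and 0.0618). The call of trans-cinnamate 4-monooxygenase (comp106234_c0_seq2, 9.20±0.475 against 4.77±0.0159) ended without any of the 4 libraries (adjusted p = 0.133 and 0.138 without water day 5 replicates 1 and 2, 0.153 and 0.101 without ABA day 5 replicates 1 and 2). Cinnamoyl-CoA reductase 1 (comp105797_c1_seq4, 37.7±3.40 against 12.8±2.29) missed it when forms of its assembly component were summed (adjusted p = 0.141). The adjusted p-values (limma) of the named transcripts that passed were 2.4e-10 to 0.0268. The ABA-conjugating enzyme abscisate beta-glucosyltransferase (comp105597_c0_seq2), named for ABA synthesis and breakdown, stood at 45.8±2.17 and 45.0±1.48 and did not pass.

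The lists called as lower for cellulose (4 lower and 0 higher of 84), gibberellin (6 and 2 of 83) and housekeeping (23 and 6 of 238) at day 5 lost the call with an estimated correlation (adjusted p = 0.0625, 0.0625 and 0.0775). The cuticle list (9 lower and 1 higher of 187) lost it without water day 0 replicate 1, water day 5 replicate 1 or 2, or ABA day 5 replicate 1 (adjusted p = 0.0506, 0.0505, 0.0799 and 0.126). Without water day 5 replicate 2 the cellulose and housekeeping lists had adjusted p = 0.0527 and 0.0799, and without ABA day 5 replicate 1 the housekeeping list had adjusted p = 0.284. With p-values adjusted over the list alone, lower and higher members were 5 and 0 for cellulose, 11 and 5 for gibberellin, 34 and 14 for housekeeping and 15 and 3 for the cuticle. Leaving out water day 5 replicate 1 or 2, or ABA day 5 replicate 1 or 2, gave 1078, 982, 1047 and 1079 transcripts.

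At day 8, ABA-injected fruit differed from water-injected fruit in 13163 transcripts, 4262 higher and 8901 lower, and the median of all transcripts was shifted by -0.20 (log2). Heat shock transcripts were higher in 146 of 252 and lower in 7 (157 and 14 adjusted over the list alone, adjusted p = 2.3e-64), with a list median of 1.48, and held 10.0%±0.308 of all RPKM against 0.982%±0.0394. The 70 kDa heat shock protein stood at 1538±47.0 against 14.9±0.347 (log2 change 6.59±0.11, SE, adjusted p = 1.2e-12). The class III small heat shock protein stood at 1376±86.3 against 3.23±0.787, the class I one at 405±30.7 against 0.833±0.447 and a mitochondrial one (comp104295_c1_seq1) at 535±3.86 against 2.13±0.547. Endoglucanase 8 (comp104453_c1_seq2) stood at 4395±143 against 338±16.1, although its list was called as lower (83 lower and 32 higher of 428). Aroma transcripts were higher in 17 of 79 and lower in 5 (17 and 7 adjusted over the list alone), with vinorine synthase (comp85231_c0_seq1) at 33.4±2.87 against 5.61±2.09. Flavonoid transcripts were split, 12 higher and 13 lower without a list call: MYB113 stood at 222±7.67 against 127±10.9 and naringenin,2-oxoglutarate 3-dioxygenase at 400.5±1.29 against 335±29.6 (adjusted p = 0.0240 and 0.131). Dihydroflavonol 4-reductase (comp105601_c0_seq1), an anthocyanin enzyme, was higher (109.8±4.79 against 26.4±1.80), but its component summed over all forms changed by -0.24 (log2, adjusted p = 0.289). Phenylalanine ammonia-lyase 1 was lower in another form (comp109367_c0_seq10, 5.94±0.497 against 44.8±6.57).

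Histone, cell cycle and photosynthesis transcripts were lower with ABA at day 8. Histones were lower in 96 of 165 and higher in 2 (list median -1.51), with histone H4 (comp103902_c1_seq8) at 51.9±1.88 against 625±17.2. Cell cycle transcripts were lower in 34 of 125 and higher in 0, with proliferating cell nuclear antigen (comp101495_c0_seq3) at 90.6±4.47 against 334±25.7. Light-harvesting and photosystem transcripts were lower in 70 of 120 and higher in 4 (median -1.49), with chlorophyll a-b binding protein P4 at 37.5±4.36 against 268±8.24. Lipoxygenase and jasmonate transcripts were lower in 30 of 81 and higher in 3, with linoleate 9S-lipoxygenase 5 (comp111446_c0_seq1) at 55.9±3.81 against 194±9.59. Gibberellin transcripts were lower in 22 of 83 and higher in 6, with gibberellin-regulated protein 1 (comp102519_c2_seq5) at 0.332±0.469 against 349±64.3 and its relative snakin-1 (comp116484_c0_seq14) at 0.208±7.07e-05 against 103±10.4. Cuticle transcripts were lower in 43 of 187 and higher in 7, and starch transcripts in 12 and 0 of 56, with a lipid-transfer-like protein (comp104388_c0_seq6) at 35.1±0.638 against 174±7.23 and inactive beta-amylase 9 at 1.14±0.0694 against 12.3±0.134. With p-values adjusted over the list alone, lower and higher members were 104 and 2 for histones, 36 and 0 for the cell cycle, 81 and 6 for photosynthesis and 34 and 3 for lipoxygenases. They were 24 and 9 for gibberellin, 58 and 8 for the cuticle and 14 and 1 for starch. Seed storage transcripts, at 0.0207%±9.62e-04 and 0.0319%±7.49e-04 of all RPKM, were lower in 6 and higher in 3 of 91 without a list call, with the vicilin-like peptide comp103260_c0_seq1 at 2.42±0.457 against 60.9±7.91.

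With ABA at day 8, the SAPK2 kinase (comp106429_c0_seq3) was lower (32.5±0.0137 against 94.0±7.85), as were auxin-responsive protein IAA27 (comp119555_c1_seq1, 7.16±0.390 against 37.5±2.35) and caffeoyl-CoA O-methyltransferase (comp100580_c1_seq1, 37.7±0.145 against 80.5±5.82). Also lower were Pru av 1 (776±5.15 against 4541±61.1), tubulin beta-6 (421±12.8 against 1236±50.7), xylem serine proteinase 1 (22.1±1.23 against 79.9±1.56), bHLH66 (comp107359_c0_seq4, 3.75±1.14 against 25.1±4.23) and squamosa promoter-binding-like protein 7 (comp105329_c0_seq4, 0.869±0.246 against 5.18±0.817). Cellulose synthase A subunit 1 (comp105077_c0_seq2), AGL21 and a subunit of NADH dehydrogenase (comp106676_c0_seq2) were listed at 0 with ABA and stood at 20.9±5.38, 11.6±0.347 and 136±32.5 with water. NAC transcription factor 25 (comp100908_c0_seq1) was higher (64.4±5.92 against 12.2±2.60), as was the ethylene-responsive factor RAP2-12 (comp97789_c0_seq1, 15.7±0.528 against 4.34±0.0377). Calls on some further transcripts depended on how values were combined. Zeaxanthin epoxidase (comp98517_c1_seq1, 12.7±0.387 against 22.8±1.57), an ABA synthesis enzyme, had adjusted p = 0.0546 with median-ratio scaling. With components summed, adjusted p was 0.358 for the invertase CWINV1 (comp104050_c2_seq2, 74.0±8.98 against 5.77±0.160) and 0.110 for 40S ribosomal protein S24-1 (comp99376_c1_seq4, listed at 0 against 30.4±3.86). Late embryogenesis abundant protein 1 (comp110838_c0_seq5, 0.679±0.107 against 26.7±0.501) turned from lower to higher (log2 change 0.53). The adjusted p-values (limma) of the named transcripts were 1.2e-12 to 0.00441.

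ABA-injected libraries at day 8 were more concentrated, with 28.6% to 28.9% of RPKM in their 100 highest transcripts against 22.2% to 24.1% in the other 12 libraries. Of the called transcripts 32.4% were higher, against 46.0% with quantile normalization and 51.5% with median-ratio scaling. With median-ratio scaling the heat shock list had 155 higher and 5 lower members, the photosynthesis list 6 and 66, and the histone list 3 and 88. Ribosomal proteins (187 lower and 9 higher of 712, 69 and 25 after that scaling) lost their list call under it (adjusted p = 0.0553). So did ABA signalling (22 lower and 5 higher of 117, adjusted p = 0.130, and 0.0909 without water day 8 replicate 2). With an estimated correlation the calls of xylem (17 lower and 2 higher of 69) and MADS-box factors (16 and 4 of 83) were lost (adjusted p = 0.128 and 0.175), as they were with median-ratio scaling (adjusted p = 0.215 and 0.0514). The xylem call also ended without water day 8 replicate 1 or ABA day 8 replicate 2 (adjusted p = 0.125 and 0.0672). The MADS-box call ended without water day 8 replicate 1 or 2 or ABA day 8 replicate 1 (adjusted p = 0.0556, 0.0671 and 0.0691). With p-values adjusted over the list alone, lower and higher members were 228 and 15 for ribosomal proteins, 28 and 7 for ABA signalling, 19 and 2 for xylem, 24 and 6 for MADS-box factors and 104 and 36 for wall softening. Leaving out water day 8 replicate 1 or 2, or ABA day 8 replicate 1 or 2, gave 7981, 8199, 7726 and 7918 transcripts.

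**Figure D3:**
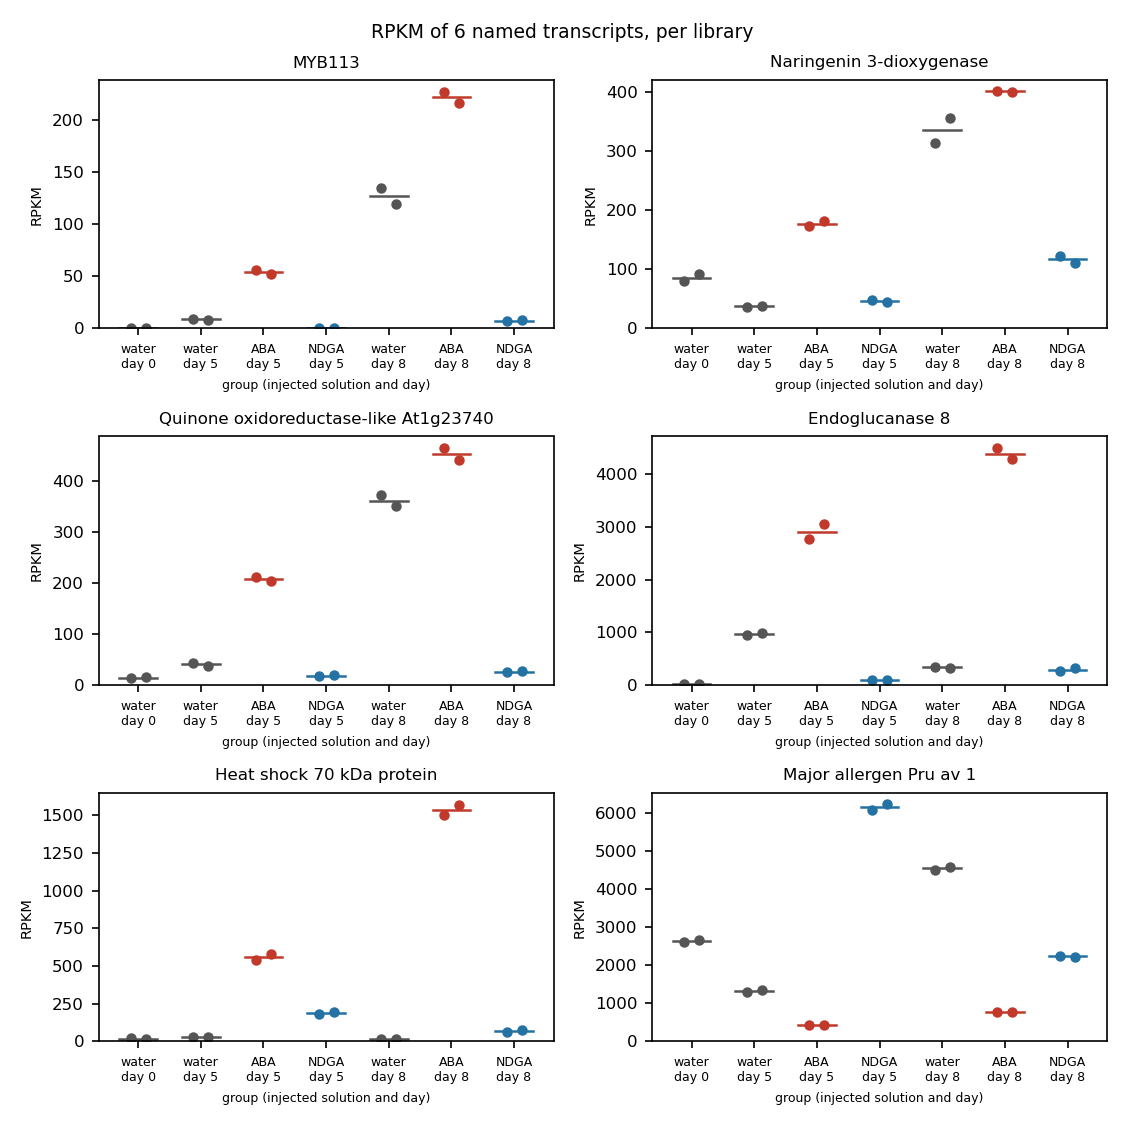
RPKM (y axis, linear from 0) of 6 named transcripts in each library (points), with a line at the mean of the 2 libraries, for the 7 groups on the x axis (grey water, red ABA, blue NDGA).

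NDGA against water at day 5 gave 1220 higher and 795 lower transcripts. The values used here hold no ABA levels, so a block of ABA synthesis cannot be told apart from other actions of NDGA. MYB113 was lower (0.541±0.348 against 8.71±1.22), and so were leucoanthocyanidin dioxygenase (comp103558_c0_seq2, 5.67±0.479 against 68.3±4.38), an anthocyanin enzyme, and endoglucanase 8 (90.4±2.43 against 964±25.6, log2 change -3.40±0.09, SE). The flavonoid list was not called, with 8 of 115 members higher and 3 lower. Photosynthesis transcripts were higher in 19 of 120 and lower in 0 (54 and 1 adjusted over the list alone, adjusted p = 8.5e-22), with chlorophyll a-b binding protein 21 at 490.1±5.18 against 132±5.76. Histones were higher in 17 of 165 and lower in 0 (34 and 0 adjusted over the list alone), with histone H4 (comp103902_c1_seq15) at 20.4±4.52 against 0.0921±0.130. Defence transcripts were higher in 33 of 212 and lower in 2 (51 and 7 adjusted over the list alone), with Pru av 1 at 6154±111 against 1317±35.9. Lipoxygenase and jasmonate transcripts were higher in 6 and lower in 2 of 81 (12 and 3 adjusted over the list alone), with TIFY 11A at 49.6±6.14 against 6.38±0.259. Heat shock transcripts were higher in 41 of 252 and lower in 9 (51 and 16 adjusted over the list alone), at 2.36%±0.0833 of all RPKM against 1.24%±0.0393. Of the class I small heat shock proteins, comp107291_c0_seq1 stood at 2246±1.70 against 57.8±9.37, comp99896_c0_seq2 at 717±78.6 against 0.384±0.543 and comp99896_c0_seq1 at 214±0.294 against 0.538±0.307, and the class III one at 630.4±37.4 against 4.51±1.60.

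Seed storage transcripts were lower with NDGA at day 5, as with ABA: 50 of 91 were lower and 4 higher (58 and 4 adjusted over the list alone), at 0.0239%±0.00122 of all RPKM. Legumin B stood at 3.69±0.0807 against 493±24.8, the 11S globulin G3 forms at 0.507±6.36e-04 against 396±22.9 and 1.09±0.221 against 447±45.8, and a legumin A form (comp93081_c0_seq1) at 0.274±0.387 against 199.8±52.5. The dehydrin list was called as lower (8 lower and 3 higher of 49, 14 and 5 adjusted over the list alone), although its named member, abscisic stress-ripening protein 2 (comp105518_c0_seq3), was higher (182±0.488 against 19.5±4.70). Gibberellin-regulated protein 1 (93.6±1.24 against 1.04±0.118), IAA27 (73.0±0.205 against 35.1±1.16), granule-bound starch synthase 1 (277±8.08 against 128±4.32) and xylem serine proteinase 1 (131±3.19 against 52.9±6.26) were higher. So were chloroplast glyceraldehyde-3-phosphate dehydrogenase A (comp102899_c0_seq1, 21.5±0.573 against 5.26±0.502), the lipid-transfer protein AKCS9 (comp102703_c0_seq2, 30.7±1.59 against 2.15±0.888) and trans-cinnamate 4-monooxygenase (17.3±1.32 against 4.77±0.0159). Cell division cycle protein 48 (comp117453_c2_seq1) stood at 5.61±0.169 with NDGA and was listed at 0 with water. Vinorine synthase (comp89769_c0_seq1, 1.27±0.321 against 13.4±0.115), NAC transcription factor 29 (comp103951_c1_seq1, 20.7±0.180 against 54.3±1.3), a 1-aminocyclopropane-1-carboxylate oxidase homolog (comp94479_c0_seq1, 1.01±0.0605 against 8.35±0.745) and cinnamoyl-CoA reductase 1 (comp96349_c2_seq8, 11.8±1.86 against 43.8±7.85) were lower.

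Several calls of NDGA against water at day 5 depended on 1 library or on the assembly forms. Abscisate beta-glucosyltransferase (27.9±3.31 against 45.0±1.48) had adjusted p = 0.0302, and 0.134 and 0.194 without water day 5 replicates 1 and 2, and 0.235 and 0.0683 without NDGA day 5 replicates 1 and 2. Protein phosphatase 2C 37 (comp115440_c0_seq6, 96.5±0.673 against 139±10.5) had adjusted p = 0.147 without water day 5 replicate 2, and 0.0993 and 0.0898 without NDGA day 5 replicates 1 and 2. Without water day 5 replicate 2 and without NDGA day 5 replicate 2, the invertase CWINV1 (comp104050_c2_seq1, 109±8.77 against 61.6±4.29) had adjusted p = 0.0741 and 0.0824, and MADS-box protein JOINTLESS (comp96748_c0_seq2, 65.3±3.02 against 38.8±3.46) 0.101 and 0.0910. Cellulose synthase A subunit 1 (8.56±4.05) and 60S ribosomal protein L8-3 (comp106479_c0_seq4, 7.12±1.02), both listed at 0 with water, lost their calls with components summed (adjusted p = 0.627 and 0.729). Lists called on few members were cellulose (3 higher and 0 lower of 84), starch (4 and 0 of 56, adjusted p = 0.0737 without water day 5 replicate 2) and lignin (3 and 1 of 133, adjusted p = 0.0645 without NDGA day 5 replicate 1). NAC factors (6 lower and 0 higher of 126) were called as lower, with adjusted p = 0.129 with an estimated correlation. With p-values adjusted over the list alone, higher and lower members were 5 and 1, 4 and 0, 11 and 2, and 1 and 11 in that order. The adjusted p-values (limma) of the named transcripts were 8.0e-12 to 0.0302, and the other 18 tested lists were not called. Leaving out water day 5 replicate 1 or 2, or NDGA day 5 replicate 1 or 2, gave 992, 985, 968 and 933 transcripts.

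At day 8, 1465 transcripts were lower with NDGA than with water and 699 higher, and pigment transcripts were among the lower ones. MYB113 stood at 7.62±0.126 against 127±10.9 (log2 change -3.89±0.21, SE), anthocyanidin 3-O-glucosyltransferase 1 (comp118873_c1_seq4) at 1.05±1.49 against 73.0±6.44, phenylalanine ammonia-lyase 1 (comp109367_c0_seq10) at 4.15±2.23 against 44.8±6.57, and the At1g23740-like quinone oxidoreductase at 26.0±1.74 against 362±15.1. Anthocyanidin reductase (comp103703_c1_seq1) was higher (108±3.60 against 22.2±0.583). Flavonoid transcripts were lower in 20 of 115 and higher in 5 (31 and 6 adjusted over the list alone, adjusted p = 8.3e-05). The aroma list was not called, with 6 of 79 lower and 2 higher (7 and 2 adjusted over the list alone). Phenylpropanoid entry transcripts were lower in 5 of 45 and higher in 0 (7 and 0 adjusted over the list alone). Photosynthesis transcripts were lower in 11 of 120 and higher in 0 (26 and 0 adjusted over the list alone), with chlorophyll a-b binding protein P4 at 142±3.90 against 268±8.24. ABA signalling transcripts were lower in 6 of 117 and higher in 0 (12 and 1 adjusted over the list alone), with the SAPK3 kinase (comp106429_c0_seq1) at 53.6±10.5 against 138±0.916. Gibberellin transcripts were lower in 13 of 83 and higher in 3 (17 and 4 adjusted over the list alone), called as lower with a mean of -0.32 but a median of 0. Gibberellin 20 oxidase 1-B (comp103306_c0_seq1) stood at 7.72±0.370 against 41.1±1.59. Heat shock transcripts were higher in 29 of 252 and lower in 1 (42 and 6 adjusted over the list alone), at 1.70%±0.0845 of all RPKM against 0.982%±0.0394. Class I small heat shock proteins stood at 480.4±57.1 against 106±5.03 (comp107291_c0_seq1) and 875±171 against 149±5.70 (comp101863_c1_seq1).

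Other transcripts lower with NDGA at day 8 were the aquaporin NIP1-2 (comp96820_c1_seq2, 5.09±0.428 against 154±16.4), beta-D-xylosidase 1 (comp112456_c0_seq3, 24.4±0.00191 against 161±5.95), a vicilin-like peptide (comp103260_c0_seq1, 2.31±0.470 against 60.9±7.91), Pru av 1 (2232±16.2 against 4541±61.1) and caffeic acid 3-O-methyltransferase (266±0.327 against 513±75.7). So were cellulose synthase A subunit 8 (comp97508_c0_seq1, 0.665±0.277 against 7.75±1.36), granule-bound starch synthase 1 (comp110537_c1_seq6, 33.4±0.815 against 92.0±7.89), auxin-induced in root cultures protein 12 (254±3.88 against 427±15.2) and ECERIFERUM 3 (comp104808_c0_seq1, 11.9±0.654 against 26.1±0.636). Higher were TIFY 11A (45.4±0.252 against 9.23±1.26), a phloem protein 2-like transcript (comp101648_c2_seq9, 284±6.52 against 130.3±5.2), a pentatricopeptide repeat protein (comp111402_c0_seq2, 1320.4±86.8 against 228±14.5) and a wall protein (comp96200_c1_seq1, 23.0±9.09 against 3.33±2.67). Seed storage transcripts were split (4 higher and 4 lower) at 0.0201%±0.00129 of all RPKM against 0.0319%±7.49e-04, without a list call. With a pseudocount of 0.1, adjusted p was 0.0884 for 1-aminocyclopropane-1-carboxylate oxidase 2 (comp93864_c0_seq2, 0.260±0.0158 against 7.18±0.558), 0.0507 for cell division cycle protein 48 (2.41±0.886 against 16.4±5.78) and 0.106 for AGL21 (0.639±0.422 against 11.6±0.347). With components summed it was 0.568 for 40S ribosomal protein S3-3 (comp103709_c1_seq9, 38.2±0.942 against 10.3±0.512) and 0.0977 for polyubiquitin 11 (comp102640_c0_seq4, 56.4±1.62 against 119.7±10.2). The directions of histone H3.2 (comp107748_c1_seq7, 3.51±2.13 against 36.3±4.67) and late embryogenesis abundant protein 1 (11.1±1.14 against 26.7±0.501) turned (log2 changes 0.16 and 0.15). Abscisate beta-glucosyltransferase (comp105597_c1_seq2, 20.4±4.56 against 6.84±1.07) had adjusted p = 0.0508 without water day 8 replicate 2 and 0.0607 without NDGA day 8 replicate 2. Without water day 8 replicate 1, or NDGA day 8 replicate 1 or 2, sucrose synthase (comp102943_c0_seq1, 59.6±1.40 against 36.4±0.446) had adjusted p = 0.0572, 0.0540 and 0.0700. NAC domain-containing protein 102 (comp101085_c0_seq1, 1107±10.4 against 1520.1±122) then had 0.136, 0.106 and 0.0825.

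Ribosomal protein (29 higher and 5 lower of 712), histone (14 and 4 of 165) and housekeeping lists (17 and 2 of 238) were called as higher with NDGA at day 8. They had adjusted p = 0.0569, 0.0887 and 0.0887 with an estimated correlation. Adjusted over the list alone the higher and lower members were 39 and 10, 21 and 5, and 32 and 7. The ribosomal call ended without NDGA day 8 replicate 1 (adjusted p = 0.152) and the histone call without water day 8 replicate 1 (adjusted p = 0.0843). The housekeeping call ended without either of these (adjusted p = 0.0903 and 0.105) and with median-ratio scaling (adjusted p = 0.0529). The adjusted p-values (limma) of the named transcripts were 9.1e-09 to 0.0116. Leaving out water day 8 replicate 1 or 2, or NDGA day 8 replicate 1 or 2, gave 923, 945, 838 and 909 transcripts. A pseudocount of 0.1 gave 1358.

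**Figure D4:**
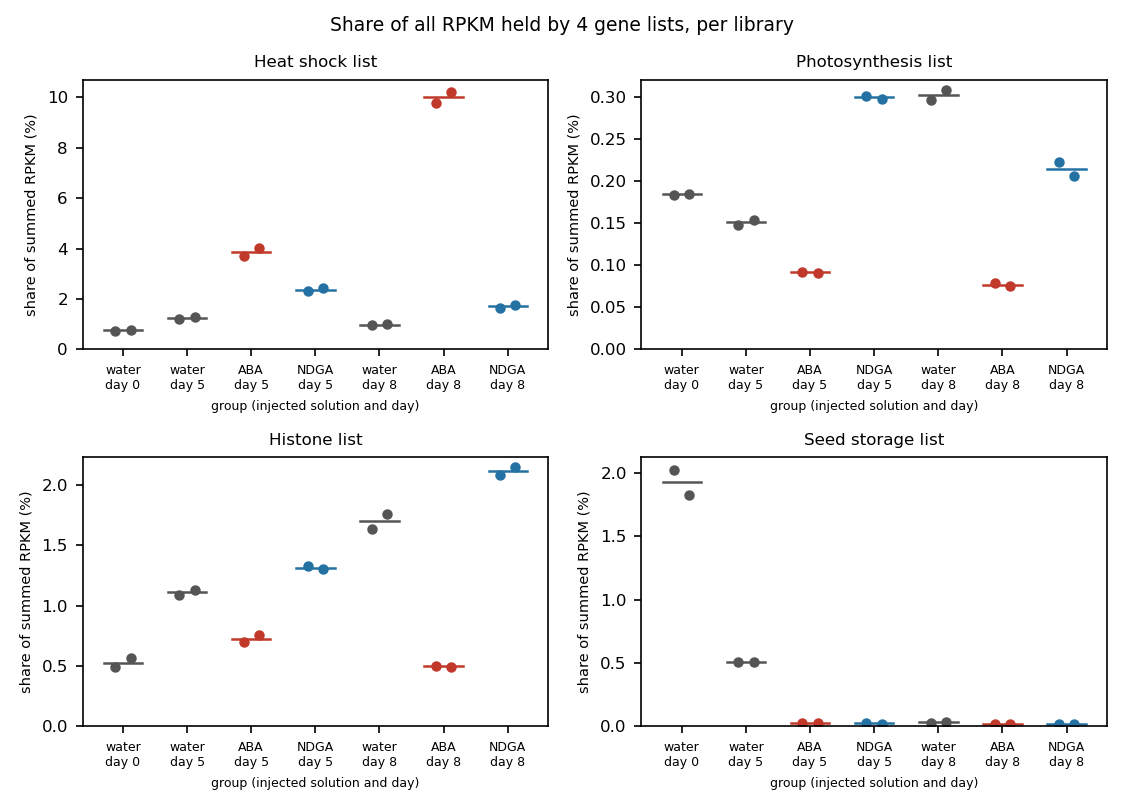
Share of summed RPKM (y axis, percent, from 0) held by the heat shock, photosynthesis, histone and seed storage lists in each mRNA library (points), with a line at the mean of the 2 libraries of each group (x axis; grey water, red ABA, blue NDGA).

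Set against each other, ABA and NDGA differed in 6390 transcripts at day 5 (3021 higher with ABA, 3369 lower) and 10918 at day 8 (3913 higher, 7005 lower, with the median of all transcripts at -0.21). Endoglucanase 8 stood at 2909±201 with ABA and 90.4±2.43 with NDGA at day 5, and at 4395±143 and 286±40.3 at day 8, and the At1g23740-like oxidoreductase at 208±5.59 and 18.0±1.85, then 454±16.7 and 26.0±1.74. Flavonoid transcripts were higher with ABA in 23 of 115 and lower in 6 at day 5, and in 25 and 11 at day 8 (adjusted p = 0.00234 and 9.8e-04), with a median of 0 at day 8. Heat shock transcripts were higher in 77 and lower in 26 of 252 at day 5, and 146 and 9 at day 8. Photosynthesis transcripts were lower with ABA in 54 and higher in 1 of 120 at day 5, and 58 and 5 at day 8, and histones in 62 and 0 of 165, then 100 and 2. With p-values adjusted over the list alone, higher and lower members at day 5 were 31 and 10 for flavonoids, 101 and 29 for heat shock, 1 and 68 for photosynthesis and 4 and 84 for histones, and at day 8 34 and 17, 163 and 16, 6 and 71, and 3 and 119. Of 19 lists called at day 5 and 12 at day 8, 13 and 10 held with an estimated correlation. The share of higher calls at day 8 was 35.8%, and 49.5% with quantile normalization and 59.6% with median-ratio scaling. Leaving out ABA day 5 replicate 1 or 2, or NDGA day 5 replicate 1 or 2, gave 3539, 3555, 3363 and 3390 transcripts at day 5. Leaving out ABA day 8 replicate 1 or 2, or NDGA day 8 replicate 1 or 2, gave 6634, 6749, 6186 and 6717 at day 8. Fits of the compared groups alone gave 81 and 1418.

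Treatments were set against ripening, on water libraries their comparison did not use. Across 99136 transcripts, which are not independent replicates, the effect of ABA at day 5 and the change from day 0 to day 8 had Pearson r = 0.165 and Spearman rho = 0.0946. The effect of NDGA had r = -0.0539 and rho = -0.108. The 3514 transcripts called as rising in ripening with a log2 change of 1 or more had a median effect of 0.16 with ABA and -0.09 with NDGA (log2, camera adjusted p = 8.8e-06 and 1.5e-04), and the 4716 that fell by as much -0.14 and 0.16 (adjusted p = 8.8e-06 and 0.00375). Against the change from day 0 to 5, the ABA effect at day 8 had r = 0.266 and rho = 0.225. NDGA had r = 0.138 and rho = 0.112. There the 3459 transcripts rising by as much had medians of 0.19 with ABA and 0.09 with NDGA (adjusted p = 4.7e-10 and 0.211, the latter not passing), and the 6825 falling ones -0.57 and -0.11 (adjusted p = 4.7e-10 and 8.8e-05). On the water change from day 0 to 8, day 8 libraries lay at 0.851 (ABA) and 0.739 to 0.747 (NDGA). Water ones, which set the scale, lay at 0.995 to 1.005, so a positive r does not mean riper fruit.

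The effects of ABA and NDGA, each against the same 2 water libraries of its day, had r = 0.295 and rho = 0.270 across transcripts at day 5, and r = 0.445 and rho = 0.423 at day 8. Unchanged groups simulated against the shared controls gave r = 0.50 at day 5 and 0.50 at day 8. The covariance was 0.106 against a simulated 0.0950 at day 5, a difference of 0.0107, and 0.219 against 0.0947 at day 8, a difference of 0.124. At day 5, 137 transcripts were higher with both compounds (14.7 expected of independent lists), 148 lower with both (7.60), 173 higher with ABA and lower with NDGA (9.61) and 120 the other way (11.7). At day 8 these counts were 300 (30.1), 996 (132), 102 (63.0) and 117 (62.8). Part of the excess may come from the shared controls, which 2 libraries do not allow to be split. Without water day 5 replicate 1 the day 5 r was 0.473.

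Known miRNAs, small RNAs that pair with mRNAs and lower them, were given as RPM (reads scaled to the clean reads of a library), and 165 names were tested, with the deposited value of each library below. Those of water day 5 replicate 2 and NDGA day 8 replicate 2 were scaled to another total, and are 2.26 and 3.55 times what the stated clean reads would give. Each library of these 2 groups was closest to the library of the same number in the other group (correlations of 0.846 and 0.857, against 0.738 and 0.689 between the replicates of these groups). In water-injected fruit, miR482e-3p stood at 636 and 799 RPM at day 5 against 214 and 172 at day 0 (log2 change 1.89±0.36, SE, adjusted p = 0.0133). There too, miR7125 stood at 24.3 and 89.3 against 3.39 and 2.77, and miR399b at 39.3 and 80.5 against 10.2 and 6.48. With ABA at day 5, miR482e-3p stood at 194 and 153. The same libraries had miR319a-3p, whose family targets TCP and MYB factors, at 6843 and 3835 against 17847 and 19280.0 with water (log2 change -1.86±0.37, SE, adjusted p = 0.0150). They had miR166h-3p at 21406 and 14110.0 against 45789 and 70109.9 (adjusted p = 0.0190). Between ABA and NDGA, miR319a-3p was lower with ABA at day 5 (6843 and 3835 against 24941 and 13409) and at day 8 (7000.4 and 7085 against 30722 and 27606, adjusted p = 0.00794). At day 5 miR5658 (18.5 and 15 against 45.4 and 45.1) and miR774b-5p (6.66 and 4.12 against 48.4 and 48.0) were lower too. With NDGA at day 8, miR482e-3p stood at 585 and 956 against 292 and 173 with water (adjusted p = 0.0476) and miR5658 at 59.9 and 47.5 against 16.3 and 14.5 (adjusted p = 0.0189). Of these 12 calls, voom on the recovered reads ended all but miR166h-3p and miR319a-3p at day 8. Quantile normalization ended all but miR7125, miR399b, and miR482e-3p and miR166h-3p with ABA (adjusted p = 0.0673 to 0.256). Fits of the compared groups alone left only miR482e-3p in both day 5 comparisons and miR319a-3p at day 8 (the others at 0.0954 to 0.362). Median-ratio scaling ended both calls of miR5658 and those of miR482e-3p between days and with NDGA (0.0709 to 0.102). Without the 2 rescaled libraries, adjusted p was 0.0610 for miR399b, 0.124 and 0.0516 for miR319a-3p and miR166h-3p with ABA at day 5, 0.141 for miR482e-3p with NDGA at day 8, and 0.0686 for miR774b-5p at day 5 and 0.0709 for miR319a-3p at day 8 between ABA and NDGA. With 1 library left out, calls ended as follows. For day 5 against day 0, adjusted p was 0.117 (miR482e-3p), 0.0839 (miR7125) and 0.125 (miR399b) without water day 0 replicate 2, and 0.0896 (miR482e-3p) and 0.102 (miR399b) without water day 5 replicate 2. For ABA against water at day 5 it was 0.0690 (miR482e-3p), 0.10 (miR319a-3p) and 0.150 (miR166h-3p) without water day 5 replicate 2, and 0.0637, 0.102 and 0.140 without ABA day 5 replicate 2. For ABA against NDGA at day 5 it was 0.103 (miR319a-3p) and 0.103 (miR5658) without ABA day 5 replicate 2, 0.138 and 0.108 without NDGA day 5 replicate 1, and 0.0564 (miR5658) without NDGA day 5 replicate 2. At day 8 it was 0.0549 (miR319a-3p) without ABA day 8 replicate 2. For miR774b-5p it was 0.0518 to 0.165 without any of the 6 water or 4 day 5 libraries of ABA and NDGA. For NDGA against water at day 8, that of miR482e-3p was 0.0842 and 0.0899 without water day 0 replicates 1 and 2, 0.190 without water day 8 replicate 2, 0.0603 and 0.0601 without ABA day 8 replicates 1 and 2 and 0.134 without NDGA day 8 replicate 2, and that of miR5658 was 0.0664 without water day 8 replicate 2.

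Most other called miRNAs were listed at 0 in both libraries of a group. The name miR166a was listed at 0 in 10 libraries and stood at 45173 and 69122 RPM in water at day 5 and 34552 and 68874 with NDGA at day 8. In turn miR166d-5p was listed at 0 in these 4 and stood at 223 and 151 at day 0, 356 and 218 and 445 and 472 with ABA and NDGA at day 5, and 260.4 and 414 in water at day 8. Above 0 with ABA at day 5 and at 0 in water were miR2089-3p (159 and 139), miR5144-5p (179.8 and 193), miR5286a (26.7 and 22.4) and miR5497 (25.5 and 15.1). The other way went miR2111a-5p (48.8 and 84.6 with water, 0 with ABA). Its adjusted p was 0.168 without the 2 rescaled libraries, 0.139 without water day 5 replicate 2, 0.0852 without ABA day 5 replicate 1 and 0.103 without ABA day 5 replicate 2. With ABA at day 8, miR5568e-3p (207 and 221), miR9471b-3p (144 and 140.1) and miR5144-5p (388 and 380.0) were above 0 and at 0 in water. The other way, miR5568f-3p was at 0 with ABA and stood at 683 and 463 in water. Other such names were miR393-3p, miR1105, miR9476-3p, miR5386 and miR5075, at up to 85.3 RPM. Narrow calls against water were those of miR5054 (189 and 213 with ABA against 4.47 and 42.6 with water at day 8, and listed at 0 with NDGA) and miR6248 (11 and 11.6 with ABA at day 8, 0 in water). For ABA, the adjusted p of miR5054 was 0.0583 to 0.204 without any 1 library but water day 8 replicate 2, and that of miR6248 0.0716 to 0.204 without any 1 but those of ABA at day 5, and 0.0812 for both without the 2 rescaled libraries. For NDGA, that of miR5054 (adjusted p = 0.0476) was 0.0513 to 0.125 without any 1 of the libraries of water at day 0, ABA at day 8 and NDGA at both days, and 0.141 without the 2 rescaled ones.

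In all, limma called 20 names between days 5 and 0 in water (14 higher, 6 lower) and 3 between days 8 and 0 (1 and 2). For the first, voom had 4 higher and 27 lower, quantile normalization 6 and 9, median-ratio scaling 10 and 12 and a fit of the compared groups alone 6 and 11, so no shared direction is claimed. With limma, 17 and 8 were called for ABA against water at days 5 and 8, 4 and 5 for NDGA against water, and 17 and 17 between ABA and NDGA. Of these calls 10, 3, 12, 7, 4, 3, 9 and 13 had a group at 0. Among the 64 names above 0 in all libraries, limma called 0 between days 8 and 0, for ABA at day 8 and for NDGA at day 5, with 11, 10 and 5 at an unadjusted p below 0.05. There voom over all names called 5, 13 and 5. Leaving out 1 library changed these counts by more than 1.5 times in 7 comparisons. For day 5 against day 0 the count was 7 (2 higher) without water day 0 replicate 2 and 9 (4 higher) without water day 5 replicate 2. For day 8 against day 0 it was 5 without water day 0 replicate 1, water day 5 replicate 1 or 2, water day 8 replicate 1, or any library of ABA at day 8 and NDGA at day 5. For ABA at day 5 it was 9 without water day 5 replicate 2 and 8 without ABA day 5 replicate 2. For NDGA it was 10 without water day 5 replicate 1 and 8 without NDGA day 5 replicate 1 at day 5. At day 8 it was 3 without water day 0 replicate 1 or 2, 9 without water day 5 replicate 1 or 2, 8 without ABA day 5 replicate 1 or 2 and 15 without NDGA day 8 replicate 1. For ABA against NDGA it was 9 without water day 0 replicate 1 or 2, 11 without water day 5 replicate 1 or 2 or ABA day 5 replicate 1, 8 without ABA day 5 replicate 2 and 7 without NDGA day 5 replicate 1 at day 5. It was 10 without ABA day 8 replicate 2 at day 8. Of 10 families tested with camera in 8 comparisons, 1 was called, miR156 and miR157 between ABA and NDGA at day 5 (adjusted p = 0.0434, but 0 of 80 tests passed with an estimated correlation). This family targets squamosa promoter-binding-like factors, and summed to 10095 and 6159 RPM with ABA against 1764 and 3680 with NDGA.

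**Figure D5:**
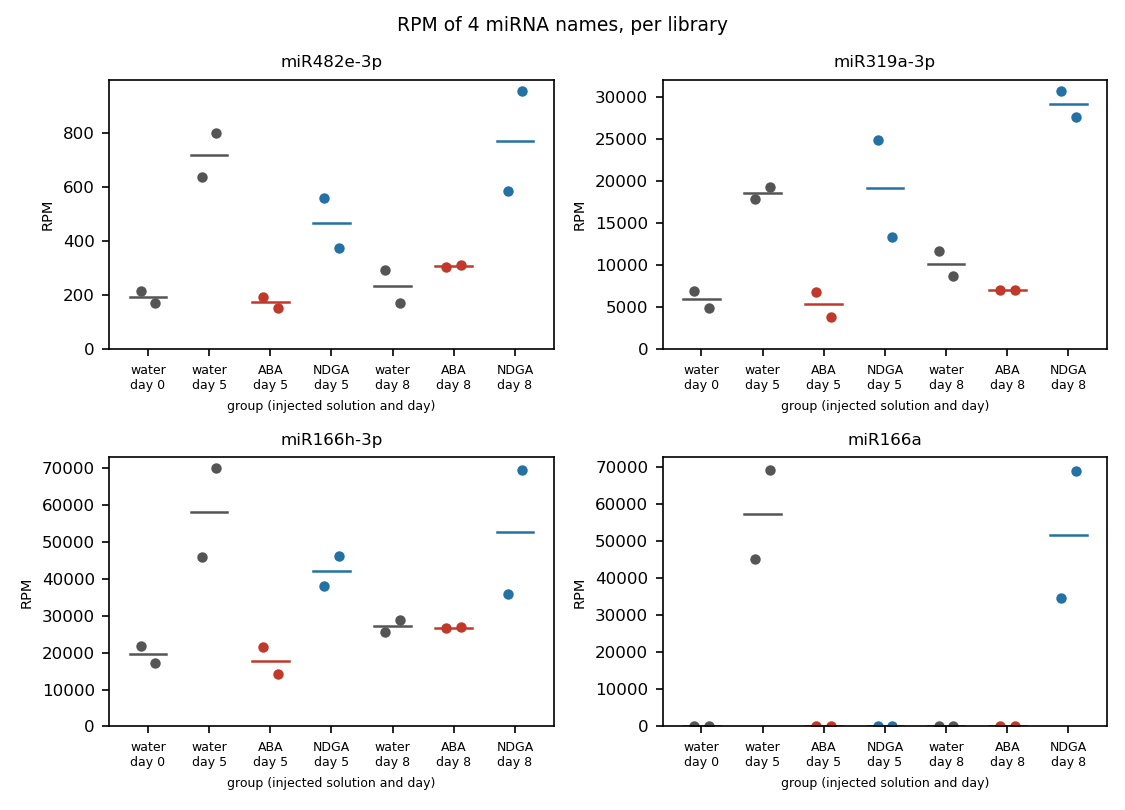
RPM (y axis, linear from 0) of 4 miRNAs in each small RNA library (points), with a line at the mean of the 2 libraries of each group (x axis; grey water, red ABA, blue NDGA).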

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

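The tests on seed storage, heat shock and miRNAs at 0 were chosen after the results were seen.

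The effect of ABA against water differed between days 8 and 5, by limma's interaction test, in 3660 transcripts (1138 higher at day 8 and 2522 lower, with the median of all transcripts at -0.20). Of these calls 31.1% were higher, against 44.1% with quantile normalization and 51.4% with median-ratio scaling. The count was 2196 and 2144 without water day 5 replicates 1 and 2, 2249 and 2196 without water day 8 replicates 1 and 2, 2295 and 2315 without ABA day 5 replicates 1 and 2, and 2296 and 2315 without ABA day 8 replicates 1 and 2. List medians of this difference (log2) were 0.77 for heat shock, -1.17 for histones, -1.0 for photosynthesis, -0.71 for lipoxygenases and jasmonate, -0.45 for flavonoids, -0.40 for the cell cycle and 1.81 for seed storage, all called by camera. Phenylpropanoid entry (-0.53), dehydrins (0.17), starch (-0.37) and defence (0.092) were called too, but with an estimated correlation had adjusted p = 0.0688, 0.0597, 0.0725 and 0.0688. These 4 also lost the call without 1 library (adjusted p = 0.0513 to 0.0964), which for at least 1 of them was any water or ABA library of days 5 and 8.

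The effect of NDGA differed between the days in 2628 transcripts (850 higher at day 8, 1778 lower). The ABA and NDGA differences share water libraries, so changes in water enter both. From day 5 to 8 there, seed storage went from 0.507% to 0.0319% of RPKM and photosynthesis from 0.151% to 0.302%. Called list medians were -1.0 for photosynthesis, -0.53 for lipoxygenases and jasmonate, -0.40 for lignin, -0.29 for phenylpropanoid entry, -0.25 for flavonoids and 1.58 for seed storage, which passed in each alternative run and with each library left out. The other 7 called lists did not, so no direction is claimed for them. Adjusted p was 0.562 and 0.309 for gibberellin (-0.20) and defence (-0.069) with 1 transcript per description, 0.109 for wall softening (-0.21) and heat shock (-0.058) with a pseudocount of 0.1, 0.136 for dehydrins (0.26) with sums per component, 0.0791 for ribosomal proteins (0.080) with an estimated correlation, and 0.0610 for starch (-0.27) without water day 8 replicate 1. All of them but gibberellin lost the call without 1 library (adjusted p = 0.0505 to 0.171), which for at least 1 list was any library but those of ABA at day 8.

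Seed storage transcripts were high at day 0 and in water at day 5. From day 0 to day 5, oleosins fell by 3.19 (median log2, n = 12 transcripts) and storage globulins by 2.11 (n = 41). The difference (-1.07, SE 0.315) treats transcripts as independent, so the same achene tissue at a smaller share stays open. So does the fruit's ABA level setting the list. NDGA moved its median to the same side as ABA (-1.58 at day 5), against the same 2 water libraries. Achene tissue carried into the day 0 and water day 5 libraries stays open: each water day 5 library held at least 0.504% of RPKM in the list, above every ABA and NDGA library of that day, but a change in the receptacle itself gives the same values.

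Heat shock transcripts were higher with ABA. With median-ratio scaling the list median at day 8 was 1.72, which argues against scaling to total reads, and members that rose lay in 89 assembly components, which argues against many forms of few genes. Warmer or otherwise stressed fruit in the ABA groups cannot be told apart from an effect of ABA, since each treatment was given to its own group of pooled fruit. Each ABA day 8 library held at least 9.78% of RPKM in the list, above both water libraries. Against the same water libraries, the share was also higher with NDGA (2.36% against 1.24% at day 5 and 1.70% against 0.982% at day 8). ABA gave 3.86%, then 10.0%, so a rise specific to ABA stays open. An effect of ABA itself was not tested apart from stress.

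Of the miRNA calls, 61 had a group at 0. Where another name of the same number was above 0 (28 calls), 7 stayed called the same way with the highest name of the number, in line with reads given to one name or another for most of them. In its 4 libraries miR166a stood at 0.965 to 0.99 of miR166h-3p, which was at 35792 to 70109.9 RPM there and 14110 to 46065 elsewhere. So nearly the same value stands under both names, and why the others list only 1 stays open. Too few reads are argued against, since the value where present corresponded to at least 67.4 reads in the libraries at 0. For the 33 calls with no other name of the number, reads given to a name with another number stay open, as the table holds no sequences, and no biological explanation was tested.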

How the results depend on the processing

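Of the alternatives, voom on recovered reads, median-ratio scaling, sums per component or number, the highest name, names above 0 in all libraries, the set without 2 rescaled libraries and the set without seed storage followers were chosen after seeing the data. With 1 library left out, the other library of its group was assumed to vary like the other groups. Same-numbered mRNA libraries deviated together weakly (correlations of 0.05 to 0.101 over 21 pairs of groups) and small RNA libraries in some pairs (-0.324 to 0.553, with 8 above 0.1, and -0.568 to 0.876 for names above 0 in all libraries). As the labels name no shared batch and not every pair lay above 0.1, the replicate numbers were not taken to pair the samples. Adding the number as a block changed 1 count by more than 1.5 times, miRNAs for ABA against NDGA at day 5 (11 with the block, 17 without). It ended the calls of miR482e-3p and miR5054 for NDGA at day 8 (adjusted p = 0.0601 for both), miR5054 and miR6248 for ABA at day 8 (0.0706 and 0.0701), miR774b-5p between ABA and NDGA (0.0505) and 3 of 13 lists on the NDGA difference between days, and no other call on named miRNAs, named transcripts or lists of the 5 comparisons.

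Apart from fits of the compared groups alone, counts of changed transcripts stayed within 1.5 times of the values reported in 105 of 107 alternatives, the others being 1358 for NDGA at day 8 with a pseudocount of 0.1 and 1680 for the NDGA difference between days with sums per component. Fits of the compared groups alone, which have fewer samples, gave 998, 823 and 45 transcripts between days 5 and 0, 8 and 0, and 8 and 5 in water, 10 and 1135 for ABA at days 5 and 8, 22 for NDGA at day 5, 81 and 1418 for ABA against NDGA, and 2372 and 1440 for the ABA and NDGA differences between days. For NDGA at day 8 limma then called 0, with 12583 at an unadjusted p below 0.05 and a smallest adjusted p of 0.168. With 1 library left out the counts were 7445 to 12420, 6181 to 10130 and 2110 to 4637 between days 5 and 0, 8 and 0, and 8 and 5, 982 to 2005 and 7726 to 12962 for ABA, 933 to 1949 and 838 to 2177 for NDGA, 3363 to 6237 and 6186 to 10816 for ABA against NDGA, and 2144 to 3446 and 1595 to 2611 for the differences between days.

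Over the 5 comparisons, 68 list calls became 65 to 70 with 1 library left out. With only the most abundant transcript of each description 9 were lost: ABA synthesis and breakdown (adjusted p = 0.111) and aroma (0.121) for day 8 against day 0, aroma (0.356) for ABA at day 5, ABA signalling (0.0741), aroma (0.0697) and MADS-box factors (0.170) for ABA at day 8, and lignin (0.191), cellulose (0.203) and NAC factors (0.107) for NDGA at day 5. Single lists and families kept their call in 439 of 476 alternatives and 931 of 952 with 1 library left out, and lost it in the others with the same direction. Sums per component ended ABA synthesis and breakdown (0.0587) and aroma (0.0564) for day 8 against day 0, gibberellin (0.0510) and cuticle (0.0735) for ABA at day 5, xylem (0.192) for ABA at day 8 and lignin (0.0704) for NDGA at day 5. Quantile normalization ended housekeeping (0.0729) and ABA signalling (0.0509) for ABA at days 5 and 8, and a pseudocount of 0.1 ABA synthesis and breakdown for day 8 against day 0 (0.0511) and MADS-box factors for ABA at day 8 (0.0534). Of 1819 values of named transcripts under alternatives, 1697 kept their call, 118 missed the threshold and 4 turned, all with sums per component: comp105601_c0_seq1 (-0.24, from 2.01) and comp110838_c0_seq5 (0.53, from -4.04) for ABA at day 8, and comp107748_c1_seq7 (0.16, from -3.13) and comp110838_c0_seq5 (0.15, from -1.20) for NDGA. With 1 library left out 2308 of 2338 kept their call.

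The correlation with ripening (r) for ABA and NDGA was 0.114 and -0.0449 at day 5 and 0.248 and 0.126 at day 8 with a pseudocount of 0.1, 0.293 and -0.0370, and 0.348 and 0.169, with the stricter filter, and 0.107 and -0.124 at day 5 without seed storage followers. With 1 library left out it was 0.133 to 0.165 and -0.0539 to -0.0424 at day 5, and 0.237 to 0.266 and 0.108 to 0.138 at day 8. Between the ABA and NDGA effects, r at day 5 was 0.364 with a pseudocount of 0.1 and 0.209 with the stricter filter, and with 1 library left out 0.250 to 0.473 at day 5 and 0.380 to 0.543 at day 8.

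The miRNA count between days 5 and 0 was 12 with the stricter filter, 31 with voom and 11 for names above 0 in all libraries. Between days 8 and 0 it was 0 with the stricter filter (limma, 11 at an unadjusted p below 0.05), 5 with voom, no filter or median-ratio scaling, 10 in the compared groups alone, 8 without 2 libraries, and 0 above 0 in all libraries. For ABA it was 29 (voom), 6 (above 0) and 11 (highest name) at day 5, and 5 (stricter), 13 (voom or the compared groups alone) and 0 (above 0) at day 8. For NDGA it was 2 (stricter, highest name or sum), 7 (no filter), 1 (compared groups alone) and 0 (above 0) at day 5, and at day 8 9 (stricter), 19 (voom), 10 (above 0), 3 (no filter, quantile normalization or median-ratio scaling), 1 (highest name), 8 (sum) and 12 (without 2 libraries). For ABA against NDGA it was 9 (stricter) and 5 (above 0) at day 5, and 28 (voom) and 4 (above 0) at day 8. Leaving out 1 library gave 7 to 24, 3 to 5, 8 to 21, 6 to 9, 4 to 10, 3 to 15, 7 to 18 and 10 to 22 in the order above. The 1 family called became 0 with an estimated correlation and 2 with quantile normalization. Named miRNAs kept their call in 468 of 527 alternatives and 770 of 840 with 1 library left out. Beside calls given with their values in the report, the compared groups alone ended miR166d-5p, miR393-3p and miR1105 for NDGA at day 5, miR5054 for ABA and NDGA at day 8, and between ABA and NDGA miR5144-5p at day 5 and miR393-3p and miR1105 at day 8 (adjusted p = 0.0569 to 0.465). No filter ended miR5054 and miR6248 for ABA (0.0689) and miR482e-3p and miR5054 for NDGA (0.0750) at day 8, and a pseudocount of 5 the latter (0.107). The cause of these shifts was not tested.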

Other observations

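The authors' deposited table of changed genes puts changed transcripts in 9 clusters, chosen on these samples and so not independent evidence of direction. Of the 4151 tested here, 3825 (92.1%) were called for ABA against water at day 8.

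For known miRNAs the authors' deposited table calls 28 between days 5 and 0 in water, 12 between days 8 and 0, 29 and 40 for ABA at days 5 and 8, and 18 and 20 for NDGA. Those tested here (27, 11, 27, 37, 16 and 16) all had the authors' sign, likewise not independent evidence. Of them 9, 0, 13, 7, 3 and 2 were also called here, of limma's 20, 3, 17, 8, 4 and 5.

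A hypothesis written before its test was that called miRNAs lower the transcripts the authors' deposited table predicts as their targets. Of 18 pairs of a miRNA and a comparison, 10 rest on a name listed at 0 in a group and so do not test it. In the other 8 (4 miRNAs), targets moved opposite to the miRNA in 3. With camera, 0 of these pairs passed in the opposite direction and 0 in the miRNA's own, with 2 at an unadjusted p below 0.05 (0.0126 and 0.0301, smallest adjusted p = 0.101), both of miR157a-5p in its own direction, and over all 18 pairs 0 passed either way. The bound set against the hypothesis was met only by this tie, so these data leave it open.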
